A study of Mus musculus with 277 samples.

How the data were processed

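Poly-A RNA from 277 flash-frozen mouse brain samples had been sequenced by the authors as unstranded 50-bp paired reads on an Illumina HiSeq2000. Reads of overlapping genes on opposite strands cannot be told apart in such libraries. The labels give each library a region (cortex, hippocampus, cerebellum or stem, here written brain stem), an age of 3 or 6 months, a cross (TPR50 F1 hybrids with DBA, FVB or C57BL6), a genotype (Wt or Tg) and an RNA integrity number (RIN) of 7.8 to 9.4. Per the labels, alignment was by TopHat2 2.07 and counting by HTSeq, with the genome builds NCBIM37 and GRCh37 named and no statement of which reads met which. No position is therefore given, and a mouse gene table was used only for gene names and for the order of genes along a chromosome.

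The deposited tables, separate for each age, held 16338 genes in 142 libraries at 3 months and 16631 genes in 135 libraries at 6 months, with 15817 genes in both. Although they were named as raw counts, the deposited values were whole numbers on a normalized scale, here treated as a score: within each table every library had the same maximum (1009489 and 589894), totals agreed within 0.0731% and 0.0298%, and the upper quartile lay between 2600 and 2601 or at 2413.5. Such agreement is what quantile normalization followed by rounding gives. Sequencing depth is therefore unknown, no interval or detection limit that needs it is given, and no test compared values of the separately normalized ages, only their Tg minus Wt differences. A count model had been planned for counts and was replaced by a linear model, because these values are not counts. The deposited values per library on the log2 scale matched the tables on shared genes at 6 months (100% of values equal) and for 96.9% of values at 3 months. Shared genes were 9467 to 9485 at 6 months and 15901 at 3 months, and the other genes of the tables were not checked in this way. Between 6730 and 7604 genes at 6 months had only values per library. The values per library were used only for genes absent from the tables.

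Each comparison was fitted with limma 3.58.1 in R 4.3.3 to log2 of the value plus 1, with moderated variances following the mean. Genes needed a value of at least 10 in at least as many libraries as the smallest group of the fit held (5 or 6). A Benjamini-Hochberg adjusted p under 0.05 was the threshold over all genes of a fit, and all tests were two-sided. Tg was compared with Wt within each region and age with the cross as a term. The cross by genotype interaction was an F test of both interaction terms. The age by genotype test compared the Tg minus Wt differences of both ages within a region, and the region by genotype test compared each region with the cerebellum within an age. The DBA and FVB crosses were compared with the C57BL6 cross among Wt libraries of a region, with age as a term. The planned comparisons of 6 with 3 months in Wt were not made, since each age was normalized by itself. Libraries were not paired by replicate number. Residuals of libraries with the same number correlated by 0.0719 to 0.145 on average at 3 months and 0.00484 to 0.0268 at 6 months, with pairs as low as -0.19. At 3 months the same number was the best match in 11 of 18 cerebellum, 9 of 16 brain stem, 6 of 18 cortex and 6 of 18 hippocampus pairs. A structure by replicate number at 3 months is therefore not excluded.

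There were 32 gene lists, fixed before the data were examined, as were the comparisons, thresholds and the rule for naming genes. Of these, 28 covered cell types, states and pathways and 4 were region markers. Each of the 28 was tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Members past the threshold were counted over all genes and adjusted over the list alone. The score of a list was the mean log2 value of its members with a mean of at least 10, and differences of scores between crosses, ages and regions were tested in limma, an analysis added after the data were seen. Mapt and Prnp were also tested by a permutation test with 100000 resamples, adjusted over 16 tests. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used for these tests and the plots, and jsonlite 2.0.0 and the package data.table (1.17.8) for reading.

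For Tg against Wt the 10 largest rises and 10 largest falls were named. These genes passed the threshold, averaged at least 1 CPM of the column total and moved the same way in all 3 crosses. Predicted genes and pseudogenes were left out of these rises and falls. Up to 4 members of each list with the smallest p past the threshold were added, whatever their level or sign per cross. Mapt, MAPT and Prnp were always named. For interactions and crosses the 6 genes with the smallest p on each side were taken. Alternatives were a pseudocount of 10, no filter, RIN as a covariate, replicate number as a block, each replicate number left out, a median-ratio scaling on top of the deposited normalization, and leaving out libraries whose profile stood apart. Other splits of the libraries were drawn 100 times per comparison, the real split included. When 200 genes were shifted in simulated data, the Tg against Wt fit recovered 90% to 98% of them at a log2 shift of 0.5 and 96% to 100% at 1, with 3.90% to 6.38% of calls false. The cross interaction recovered 54% to 79% and 81% to 97%. All libraries of the series were used. Some genes that met the naming rule are not reported here.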

Results

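RNA was measured in 277 brain libraries of F1 hybrids between TPR50 mice, a line that carries a tau transgene, and the DBA, FVB or C57BL6 strain. Wt (140 libraries) and Tg (137 libraries) animals were sampled in cortex, hippocampus, brain stem and cerebellum at 3 and 6 months, which gave 48 groups of 5 or 6 libraries. Values were quantile-normalized by the authors, so depth per library is unknown. Errors beside means are SD and errors beside log2 differences (Tg minus Wt) are SE. The number of Tg and Wt libraries was 18 and 18 in cortex, hippocampus and cerebellum and 17 and 17 in brain stem at 3 months. At 6 months it was 17 and 17 in cortex, 17 and 18 in hippocampus, and 16 and 17 in brain stem and cerebellum. By marker genes of the regions, 275 of 277 libraries scored highest in the region of their label, with each score taken relative to the median of that region's own libraries. Without this step brain stem libraries scored 9.14 to 10.03 for their own markers and 7.86 to 10.27 for cerebellum markers. The exceptions were cortex libraries at 3 months of the C57BL6 cross, Wt replicate 2 and Tg replicate 2.

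The transgene was sought in the tau gene, which encodes the microtubule-associated protein tau. No human MAPT was listed, and values at mouse Mapt were higher in Tg in all 8 comparisons (permutation test, adjusted p = 4e-05, the smallest it can give here). In cortex at 6 months Mapt averaged 30672 ± 1107 in Tg and 24007 ± 529.6 in Wt, and all 17 Tg libraries lay above all Wt libraries. The log2 difference of group means was 0.26 and 0.35 in cortex at 3 and 6 months, 0.30 and 0.33 in hippocampus, 0.25 and 0.26 in brain stem, and 0.15 and 0.18 in cerebellum. Tg lay above every Wt library in each comparison except for 1 library in brain stem (16 of 17 above) and 1 in cerebellum (17 of 18 above) at 3 months. Prnp, the prion protein gene, differed little. As a plain difference of group means, without the cross term of the limma fits, its log2 difference was 0.08 in cortex (adjusted p = 0.0444, permutation test) and 0.08 in hippocampus (adjusted p = 0.00122) at 6 months, with 2 of 17 and 11 of 17 Tg libraries above all Wt, and -0.08 in brain stem at 3 months (adjusted p = 0.000747). It did not pass in the other 5 comparisons (adjusted p from 0.0696 to 0.892). No separate value was given for human tau, and whether its reads were counted at Mapt is unknown. The height of the transgene itself is therefore not given.

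Genes that lie beside Prnp marked Tg libraries far more sharply. Prnd, which encodes the prion-like protein doppel, averaged 4202 ± 579 in Tg and 11.4 ± 3.03 in Wt cortex at 3 months (log2 difference 8.44 ± 0.11, adjusted p = 3.16e-37). The endogenous retroviral gene Erv3 averaged 24887 ± 1478 and 33.3 ± 10.2. Both genes separated all Tg from all Wt libraries in every region and age. Rassf2, on the other side of Prnd, rose in hippocampus at 3 months from 2842 ± 312 in Wt to 5715 ± 316 in Tg (log2 difference 1.01 ± 0.04, adjusted p = 3.58e-23), and was above the Wt range in 18 of 18 libraries.

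**Figure D1:**
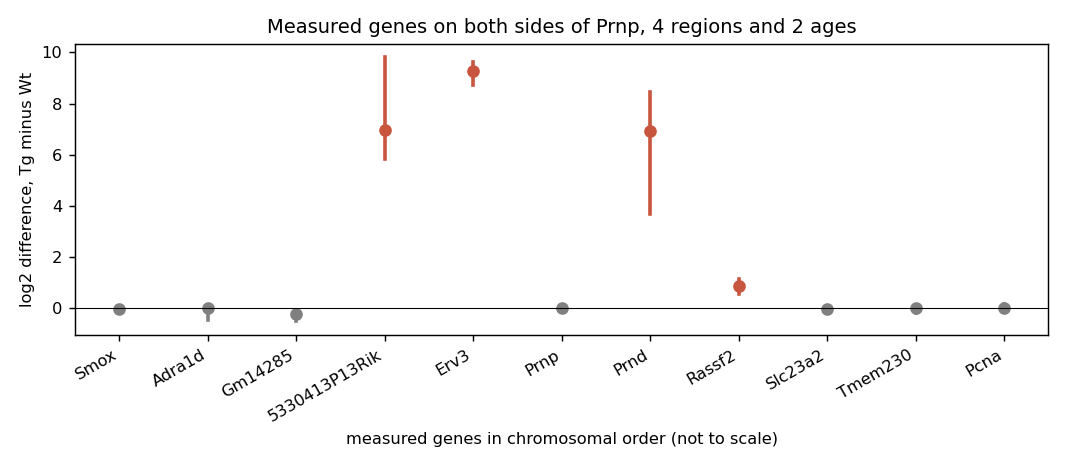
Measured genes in their order around Prnp on the horizontal axis and the Tg minus Wt log2 difference on the vertical axis. Lines run from the lowest to the highest of the 8 comparisons, dots are medians, and red marks genes higher in Tg in all 8 (Erv3 8.72 to 9.61, Rassf2 0.57 to 1.14), while Prnp lay between -0.07 and 0.09.

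In cortex at 3 months, genes of astrocyte reaction, interferon response and antigen presentation were higher in Tg. The means, SD and ranges there include the C57BL6 replicate 2 libraries of Wt and Tg described below, whose profiles stood apart. Gfap, the intermediate filament of reactive astrocytes, rose from 5129 ± 2441 in Wt to 13134 ± 5165 in Tg (log2 difference 1.35 ± 0.15, adjusted p = 6.05e-08). The complement gene C4b rose from 615 ± 186 in Wt to 1415 ± 561 in Tg (log2 difference 1.16 ± 0.13, adjusted p = 2.65e-07) and lay above all Wt libraries in 11 of 18 Tg libraries. The MHC class I gene H2-Q7 and Nlrc5, the activator of MHC class I transcription, rose by 1.15 ± 0.14 and 1.13 ± 0.13. Oasl2, Irf7, Rsad2 and Ifit3, which interferon induces, rose by 1.05, 0.87, 0.83 and 0.78. The largest falls included Gli1, the transcription factor that reports Hedgehog signalling, which fell from 148 ± 51.4 in Wt to 77.9 ± 77 in Tg (log2 difference -1.11 ± 0.18, adjusted p = 1.71e-04) and was below all Wt libraries in 17 of 18. Sfrp5, a secreted inhibitor of Wnt signalling, fell from 102 ± 168 to 29.8 ± 13.6 (log2 difference -1.33 ± 0.25), and without the C57BL6 Wt replicate 2 library described below by 1.10, and Apln, Entpd2 and Heyl fell by 0.51, 0.62 and 0.61.

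In that comparison 247 of 16212 genes passed (170 up, 77 down). Of the interferon response list 17 of 21 members rose (19 adjusted over the list alone, median log2 difference 0.52), of MHC class I presentation 8 of 13 (10 adjusted over the list alone), of complement and Fc receptors 9 of 17 (15 adjusted over the list alone) and of reactive astrocytes 8 of 18 (10 up and 1 down adjusted over the list alone). Disease-associated microglia had 2 of 18 members up, Tyrobp (0.26) and Lyz2 (0.26), and 7 adjusted over the list alone. These 5 lists passed camera with the preset correlation (adjusted p from 1.72e-56 to 1.38e-06) and with an estimated correlation (adjusted p from 4.16e-05 to 0.0195). A further 14 lists passed only with the preset correlation, among them homeostatic microglia, lysosome and myelin upward and cholesterol synthesis, oxidative phosphorylation and meninges downward (adjusted p from 0.0541 to 0.485 with an estimated correlation). Cholesterol synthesis had 0 members past the limma threshold over all genes and 8 of 18 down adjusted over the list alone (median -0.11). Wt replicate 2 of the C57BL6 cross had a cortex marker score of 7.59 where the other cortex libraries of 3 months lay between 11.97 and 12.19, and Tg replicate 2 scored 11. Without the Wt library 549 genes passed, and without both 893 (586 up, 307 down), and without both 8 of the 14 lists no longer passed, among them oxidative phosphorylation (adjusted p = 0.129), axon injury response (0.129), neurofilament (0.129) and heat shock (0.449). The axon injury call also ended with RIN as a covariate (0.109). Leaving out all libraries of a replicate number gave 143 to 644 genes.

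In hippocampus at 3 months more genes rose than fell (512 up, 91 down of 16194). Gfap rose from 13088 ± 1742 in Wt to 24421 ± 5668 in Tg (log2 difference 0.88 ± 0.08, adjusted p = 1.85e-10) and C4b from 1327 ± 251 in Wt to 2894 ± 698 in Tg (log2 difference 1.11 ± 0.09, adjusted p = 5.46e-12). All 18 Tg libraries exceeded every Wt library for Gfap and 17 of 18 for C4b. Genes of MHC class II presentation, which displays peptides on antigen-presenting cells, rose from low levels. Cd74, the invariant chain, rose from 43.6 ± 22.5 in Wt to 114 ± 92.6 in Tg (log2 difference 1.11 ± 0.26, adjusted p = 0.00822), above the Wt range in 7 of 18 libraries, and H2-Aa and H2-Ab1 rose by 1.13 and 0.94. In FVB, C57BL6 and DBA these rises were 2.30, 0.71 and 0.33 for Cd74, 2.56, 0.35 and 0.48 for H2-Aa and 1.54, 0.90 and 0.38 for H2-Ab1. No gene passed the cross by genotype test there. Myelin genes were also higher. Opalin, a protein of mature oligodendrocytes, rose from 753 ± 162 to 1079 ± 209.9 (log2 difference 0.53 ± 0.10), and Mog and Cldn11 rose by 0.42 ± 0.08 and 0.47 ± 0.10. Gli1 fell from 154 ± 28.7 in Wt to 74.0 ± 16.9 in Tg (log2 difference -1.06 ± 0.09, adjusted p = 1.62e-11), and Agt, the angiotensinogen gene of astrocytes, and Etnppl fell by 0.45 and 0.44.

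The count of members that rose in hippocampus at 3 months was 15 of 21 for interferon response, 8 of 13 for MHC class I, 4 of 6 for MHC class II, 12 of 17 for complement, 8 of 18 for disease-associated microglia, 7 of 13 for homeostatic microglia, 9 of 18 for reactive astrocytes, 12 of 18 for myelin, 3 of 13 for oligodendrocyte precursors and 10 of 21 for lysosome. The same counts were 15, 10, 4, 14, 13, 7, 11, 16, 6 and 15 adjusted over the list alone, with none down. All 10 lists passed camera (adjusted p from 4.50e-35 to 2.53e-04) and also with an estimated correlation (adjusted p from 2.98e-05 to 0.0389). Vascular cells passed only with the preset correlation (adjusted p = 0.181 with an estimated correlation). Synaptic vesicle (median 0.02, adjusted p = 0.176), inhibitory neurons (0.01, adjusted p = 0.136) and immediate early genes (-0.05, adjusted p = 0.335) did not pass. Leaving out all libraries of a replicate number gave 357 to 532 genes in place of 603.

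In brain stem at 3 months about as many genes fell as rose. Gli1 fell from 369 ± 59.5 in Wt to 161 ± 51.6 in Tg (log2 difference -1.21 ± 0.09, adjusted p = 2.63e-12) and Itih3, which encodes a heavy chain that binds hyaluronan, fell from 6618 ± 637 in Wt to 3666 ± 611 in Tg (log2 difference -0.85 ± 0.05, adjusted p = 9.35e-15). For both genes all 17 Tg libraries lay below all Wt libraries. Sfrp5 fell from 1045 ± 154 to 569.5 ± 72.6 (log2 difference -0.87 ± 0.06), Heyl, a Notch target, by 0.72, and Gria1, a subunit of AMPA glutamate receptors, fell from 12928 ± 746 to 10743 ± 899.6 (log2 difference -0.28 ± 0.03). Among astrocyte identity genes the connexin gene Gjb6 and the growth factor receptor gene Fgfr3 fell by 0.27 and 0.17, while the water channel gene Aqp4 rose by 0.22. Rufy4, near 10 in Wt of the FVB and C57BL6 crosses, rose by 3.53 ± 0.29, H2-Q7 by 1.07 ± 0.12 and C4b from 1376 ± 176 to 1995 ± 301 (log2 difference 0.54 ± 0.06). Gfap rose from 18224 ± 3298 in Wt to 24619 ± 4549.6 in Tg (log2 difference 0.44 ± 0.06, adjusted p = 1.65e-06).

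Altogether 431 of 16251 brain stem genes passed (219 up, 212 down). Of the interferon list 13 of 21 members rose (21 adjusted over the list alone) and of MHC class I 9 of 13 (10 adjusted over the list alone). Of cholesterol synthesis 8 of 18 fell (16 adjusted over the list alone), with Insig1, the sensor of sterols, at -0.19 ± 0.03 and Nsdhl at -0.14 ± 0.03. Of astrocyte identity 6 of 15 fell and 1 rose (9 and 1 adjusted over the list alone). Of myelin 4 of 18 rose (10 adjusted over the list alone), of MHC class II 2 of 6 (4 adjusted over the list alone), and of reactive astrocytes 3 rose and 1 fell of 18 (5 and 1 adjusted over the list alone). These 7 lists passed camera with an estimated correlation (adjusted p from 2.36e-04 to 0.0204). Another 9 passed only with the preset correlation, among them complement, both microglia lists and lysosome upward and choroid plexus and heat shock downward (adjusted p from 0.0614 to 0.57 with an estimated correlation). The heat shock call also ended with RIN as a covariate (0.0523).

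Averaged over the crosses, cerebellum had the largest median rise of the interferon list at 3 months (0.91), but in the DBA cross alone the score rose by 0.27 there and by 0.51 in cortex. Oasl2 rose from 122 ± 57.7 in Wt to 551 ± 427 in Tg (log2 difference 1.83 ± 0.18, adjusted p = 1.90e-09), above all Wt libraries in 11 of 18. Irf7, the transcription factor that amplifies interferon signals, rose from 70.5 ± 24.5 to 264 ± 191 (log2 difference 1.56 ± 0.18), and Usp18, Ifit1, Ddx60 and Rsad2 by 1.73, 1.55, 1.46 and 1.37. The complement gene C1qa, made by microglia, rose by 0.43 ± 0.04, and the microglial receptor gene Trem2 by 0.31 over the crosses (0.51 in C57BL6, 0.45 in FVB and -0.03 in DBA). Gria1 fell from 29409 ± 1572 in Wt to 23821 ± 1851 in Tg (log2 difference -0.31 ± 0.03, adjusted p = 1.05e-09), Myoc from 97.3 ± 31.9 to 50.0 ± 14.0 (log2 difference -0.93 ± 0.13), and Wif1 and Wnt6 of Wnt signalling by 0.74 and 0.65. Slc22a6 and Slc6a13, transporters of the meninges, fell by 0.51 and 0.45, and Apoe fell by 0.11.

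Of 16083 cerebellar genes 878 passed (390 up, 488 down). All 21 interferon genes rose (21 adjusted over the list alone, median 0.91), as did 12 of 13 MHC class I genes (13 adjusted over the list alone) and 11 of 17 complement genes (13 adjusted over the list alone). Astrocyte identity had 8 of 15 members down (8 adjusted over the list alone), such as Mlc1 (-0.24) and Ntsr2 (-0.19), and cholesterol synthesis 5 of 18 (13 adjusted over the list alone). These 5 lists passed camera with either correlation (adjusted p from 3.28e-05 to 0.00628 with an estimated correlation). Homeostatic microglia, MHC class II, myelin and lysosome upward, and meninges and heat shock downward, passed only with the preset correlation (adjusted p from 0.0539 to 0.659 with an estimated correlation). Meninges had 2 of 11 genes down and 8 adjusted over the list alone. Reactive astrocytes did not pass (adjusted p = 0.115): 1 member rose and 4 fell, among them Cd44, S100a6 and Fbln5.

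**Figure D2:**
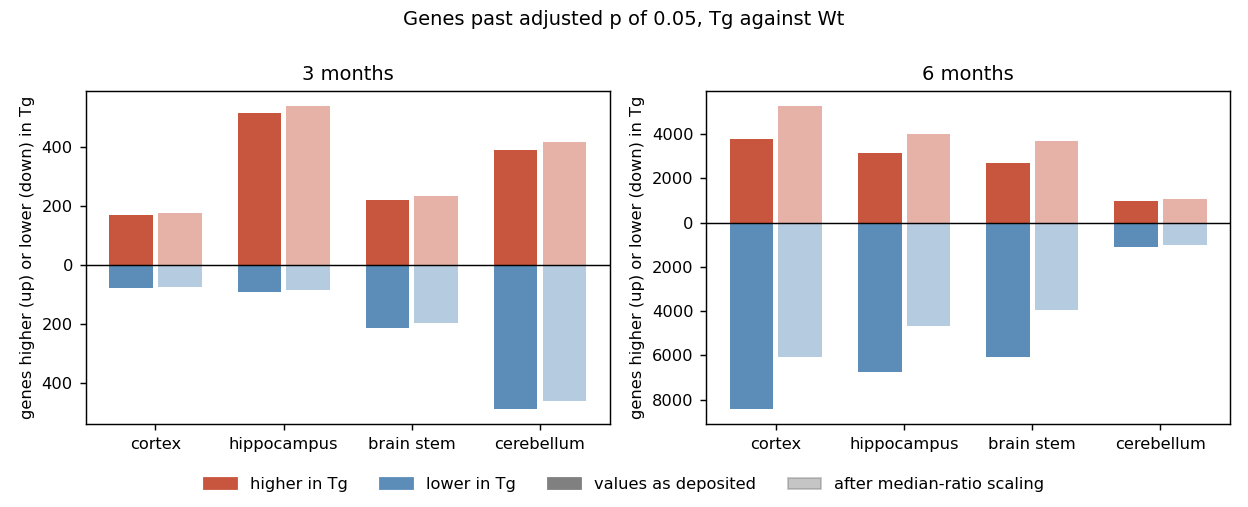
Number of genes past the threshold between Tg and Wt, higher and lower in Tg, for each region and age, with the values as deposited and after median-ratio scaling. At 6 months 12219 cortex genes passed and 2084 cerebellar genes, and scaling lowered the share of falling genes in cortex from 69.1% to 53.7%.

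At 6 months cortex differed in most genes. The chemokine gene Cxcl10 rose from 4.71 ± 3.53 in Wt to 701 ± 313 in Tg (log2 difference 6.99 ± 0.27, adjusted p = 8.54e-21), and the chemokine gene Ccl2 from 2 ± 1.80 to 265 ± 161 (log2 difference 6.41 ± 0.31). Microglial genes of the disease-associated state followed, Itgax from 9.06 ± 2.99 to 576 ± 372 (log2 difference 5.53 ± 0.30) and Clec7a, a receptor for glucans, by 4.99 ± 0.28. Gfap rose from 4800.0 ± 414 in Wt to 75748 ± 19156 in Tg (log2 difference 3.94 ± 0.10, adjusted p = 4.40e-27) and C4b from 875 ± 207 to 19783 ± 8161 (log2 difference 4.38 ± 0.16). Mmp3, a matrix protease, and Gdf15, a stress cytokine, rose by 6.93 ± 0.37 and 6.63 ± 0.33. For Cxcl10, Gfap and C4b all 17 Tg libraries lay above all Wt libraries. Atf3, a factor induced by axon injury and stress, rose from 44.7 ± 24.8 to 169 ± 67.7 (log2 difference 2.01 ± 0.25). Gli1 fell from 147 ± 32.2 in Wt to 43.3 ± 13 in Tg (log2 difference -1.74 ± 0.13, adjusted p = 1.17e-13), in 17 of 17 libraries below the Wt range, and Etnppl, an astrocyte enzyme, fell (log2 difference -1.69). Falls of neuronal genes were smaller: the NMDA receptor subunit Grin2a fell from 1518 ± 191 to 1127 ± 272 (log2 difference -0.47 ± 0.07), the release protein Snap25 from 114090.0 ± 6109 to 97304 ± 8739.9 (log2 difference -0.23 ± 0.03), and the neurofilament genes Nefm and Nefh by 0.43 and 0.40.

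Of 16480 cortex genes 12219 passed (3779 up, 8440 down), and after median-ratio scaling 5252 rose and 6097 fell. Every measured member of interferon response (25, median 3.13), complement (18, 2.40), MHC class I (13, 2.50) and homeostatic microglia (15, 1.13) rose, the same numbers as adjusted over the list alone. Disease-associated microglia had 21 up and 3 down of 24, reactive astrocytes 19 up and 1 down of 21, MHC class II 6 up of 7, lysosome 19 of 21, myelin 17 of 18, oligodendrocyte precursors 11 of 13 and vascular cells 13 up and 2 down of 15, unchanged when adjusted over the list alone. All 18 genes of cholesterol synthesis fell (18 adjusted over the list alone, median -0.29), such as Fdps from 836 ± 54.3 to 611 ± 86.7 (log2 difference -0.46 ± 0.05). Of synaptic vesicle genes 20 of 21 fell (20 adjusted over the list alone), but 9 after scaling, of the excitatory postsynapse 13 of 20 (13 adjusted over the list alone), but 8 with 3 up after scaling, and of oxidative phosphorylation 21 of 25 (21 adjusted over the list alone), but 11. Inhibitory neurons had 13 of 16 down and 1 up (13 and 1 adjusted over the list alone). Camera passed 15 lists with the preset correlation (interferon adjusted p = 7.55e-28, cholesterol synthesis 1.74e-04, synaptic vesicle 0.00728) and none with an estimated correlation (adjusted p from 0.1 to 0.572 with an estimated correlation). Oxidative phosphorylation passed before scaling (adjusted p = 0.0147) and not after (0.0925), and inhibitory neurons (adjusted p = 0.0497) not with RIN as a covariate (0.0605). The postsynapse, axon injury (6 up, 6 down), unfolded protein (5 up, 5 down), T cell (2 up, 2 down) and meninges (3 up, 1 down) lists did not pass. The T cell score, a mean over members, was nonetheless higher in Tg than in Wt in each cross. It was 7.45 ± 0.16 against 6.22 ± 0.20 in C57BL6, 7.13 ± 0.17 against 5.89 ± 0.23 in DBA and 7.53 ± 0.17 against 5.92 ± 0.31 in FVB. Camera pointed up where the median was negative for astrocyte identity (-0.06), choroid plexus (-0.08), red blood cells (-0.09) and T cells (-0.03), and after scaling the medians of astrocyte identity and T cells were positive.

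In hippocampus at 6 months 9907 of 16473 genes passed (3130 up, 6777 down; 4021 and 4673 after scaling). Cxcl10 rose from 6.83 ± 4.27 in Wt to 430.2 ± 328 in Tg (log2 difference 5.31 ± 0.38, adjusted p = 1.09e-12), Cd74 from 43.5 ± 14.4 to 1008 ± 804 (log2 difference 3.99 ± 0.34), C4b from 1975 ± 532 to 16235 ± 7771 (log2 difference 2.90 ± 0.19) and Gfap from 13345 ± 1606 in Wt to 82642 ± 36949 in Tg (log2 difference 2.49 ± 0.16, adjusted p = 3.28e-14), and 17 of 17 Tg libraries exceeded all Wt libraries for Cxcl10. Itgax and Clec7a rose by 4.16 ± 0.44 and 4.02 ± 0.44, and the tight junction gene of myelin Cldn11 by 0.99 ± 0.11. Ttr, the main product of the choroid plexus, fell from 3939 ± 8917 in Wt to 387 ± 279.7 in Tg (log2 difference -2.04 ± 0.55, adjusted p = 0.00203) and varied widely, with 1 of 17 Tg libraries below all Wt libraries. Slc17a6, a vesicular glutamate transporter, fell from 870.1 ± 212 to 527 ± 225 (log2 difference -0.83 ± 0.19), and Gli1 and Agt by 1.62 and 1.12.

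All measured members of the interferon, complement, MHC class I and homeostatic microglia lists rose there as well (25, 18, 13 and 15, and as many adjusted over the list alone), with medians of 2.46, 1.87, 1.85 and 0.92. Reactive astrocytes had 20 up and 1 down of 21 and disease-associated microglia 21 up and 1 down of 24, myelin 17 of 18 and lysosome 19 of 21 up, also adjusted over the list alone. All 18 cholesterol genes fell (18 adjusted over the list alone), as did 16 of 20 postsynaptic and 17 of 21 vesicle genes (16 and 17 adjusted over the list alone), of which 9 and 8 fell after scaling. Neurofilament and microtubule genes had 15 of 19 down (15 adjusted over the list alone), with Kif5a and Kif5c, motors of axonal transport, both at -0.24. The 17 lists past camera, interferon with the smallest adjusted p (2.77e-25), all lost the call with an estimated correlation (adjusted p from 0.0832 to 0.563 with an estimated correlation). Choroid plexus had 7 of 10 members down (7 adjusted over the list alone) and did not pass camera (adjusted p = 0.0831), except after scaling (0.0234). Heat shock, which passed narrowly (adjusted p just under 0.05), did not pass after scaling (0.0543). For axon injury response (median -0.15) and meninges (-0.11) camera pointed up and did not pass.

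In brain stem at 6 months 8769 of 16519 genes passed (2706 up, 6063 down; 3704 and 3949 after scaling). Gdf15 and Cxcl10 rose from near absence, Cxcl10 from 6.47 ± 4 in Wt to 487 ± 325 in Tg (log2 difference 5.58 ± 0.40, adjusted p = 1.85e-12), and Itgax from 13.5 ± 4.80 to 521 ± 524 (log2 difference 4.39 ± 0.38). C4b rose from 1633 ± 162 to 17755 ± 10429 (log2 difference 3.12 ± 0.24) and Gfap from 16336 ± 2781 in Wt to 64856 ± 27734 in Tg (log2 difference 1.86 ± 0.15, adjusted p = 3.68e-11), and all 16 Tg libraries lay above all Wt libraries for Cxcl10 and Gfap. The immediate early genes Egr2 and Junb rose by 1.2 and 0.84, and Th, the rate-limiting enzyme of catecholamine synthesis, by 0.22 ± 0.05. Gli1 fell from 339 ± 64.4 in Wt to 96.6 ± 39.0 in Tg (log2 difference -1.86 ± 0.14, adjusted p = 2.87e-12) and Gria1 from 11919 ± 765 to 9151 ± 1137 (log2 difference -0.39 ± 0.03), both in 16 of 16 libraries below the Wt range. Ttr fell from 1778 ± 4205 to 94.2 ± 124 (log2 difference -2.39 ± 0.67) with 0 of 16 Tg libraries below all Wt libraries (adjusted p = 0.00373), and Gabra6, a marker of cerebellar granule cells, fell by 1.01 (adjusted p = 0.0309) with 3 of 16 below all Wt libraries. Cerebellum marker scores varied among the brain stem libraries of both ages (7.86 to 10.27), and their part in the Gabra6 fall was not tested.

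Members that rose in brain stem at 6 months were 25 of 25 in interferon response, 18 of 18 in complement, 13 of 13 in MHC class I, 15 of 15 in homeostatic and 21 of 24 in disease-associated microglia (2 fell), 19 of 21 in reactive astrocytes (1 fell), 18 of 21 in lysosome (1 fell), 13 of 18 in myelin and 6 of 7 in MHC class II, and as many adjusted over the list alone. All 18 cholesterol genes fell, and 11 of 15 heat shock genes (18 and 12 adjusted over the list alone). Vesicle genes had 15 down and 1 up of 21 (16 and 1 adjusted over the list alone), but 6 down and 2 up after scaling, and oxidative phosphorylation 14 of 25 down (14 adjusted over the list alone), but 4 after scaling. None of the 16 camera calls held with an estimated correlation (adjusted p from 0.0982 to 0.544 with an estimated correlation). The vesicle and oxidative phosphorylation calls (adjusted p = 0.0201 and 0.0461) also ended with scaling (0.0533 and 0.254). The monoaminergic neuron call (adjusted p = 0.0414, median 0.08) ended with RIN as a covariate (0.0506) and with scaling (0.0832).

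Cerebellum at 6 months kept an interferon response with little Gfap change. Oasl2 rose from 156 ± 77.3 in Wt to 850.4 ± 564 in Tg (log2 difference 2.13 ± 0.19, adjusted p = 2.23e-10), Cxcl10 from 15.4 ± 19.6 to 73.2 ± 37.5 (log2 difference 2.83 ± 0.31), and C4b from 604 ± 181 to 1524 ± 662 (log2 difference 1.24 ± 0.12), while Gfap rose from 4965 ± 702 in Wt to 6333 ± 1289 in Tg (log2 difference 0.33 ± 0.06, adjusted p = 3.37e-04). Itgax and Clec7a rose by 1.57 and 1.28. Gria1 fell from 27819 ± 1551 in Wt to 20204 ± 1268 in Tg (log2 difference -0.46 ± 0.03, adjusted p = 3.61e-15), in 16 of 16 libraries below all Wt libraries, and Slc1a3, the glutamate transporter of Bergmann glia, from 66199 ± 2867 to 54564 ± 6094 (log2 difference -0.29 ± 0.03). Myoc, Aox3 and Wif1 fell by 1.34, 1.19 and 0.96, and Bmp4 of oligodendrocyte precursors by 0.68.

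There 2084 of 16311 genes passed (959 up, 1125 down). All 25 interferon and 13 MHC class I genes rose, 16 of 18 complement genes (18 adjusted over the list alone) and 11 of 23 disease-associated microglia genes (12 up and 1 down adjusted over the list alone), while 10 of 15 astrocyte identity genes fell and 1 rose (11 and 1 adjusted over the list alone). These 5 lists passed camera also with an estimated correlation (adjusted p from 3.38e-04 to 0.0318). The other 9 calls did not hold, among them homeostatic microglia, lysosome and immediate early genes upward and cholesterol synthesis (11 of 18 down, 12 adjusted over the list alone), meninges (6 of 11 down, 9 adjusted over the list alone) and heat shock downward (adjusted p from 0.0611 to 0.422 with an estimated correlation). Leaving out all libraries of a replicate number gave 1389 to 1969 genes.

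**Figure D3:**
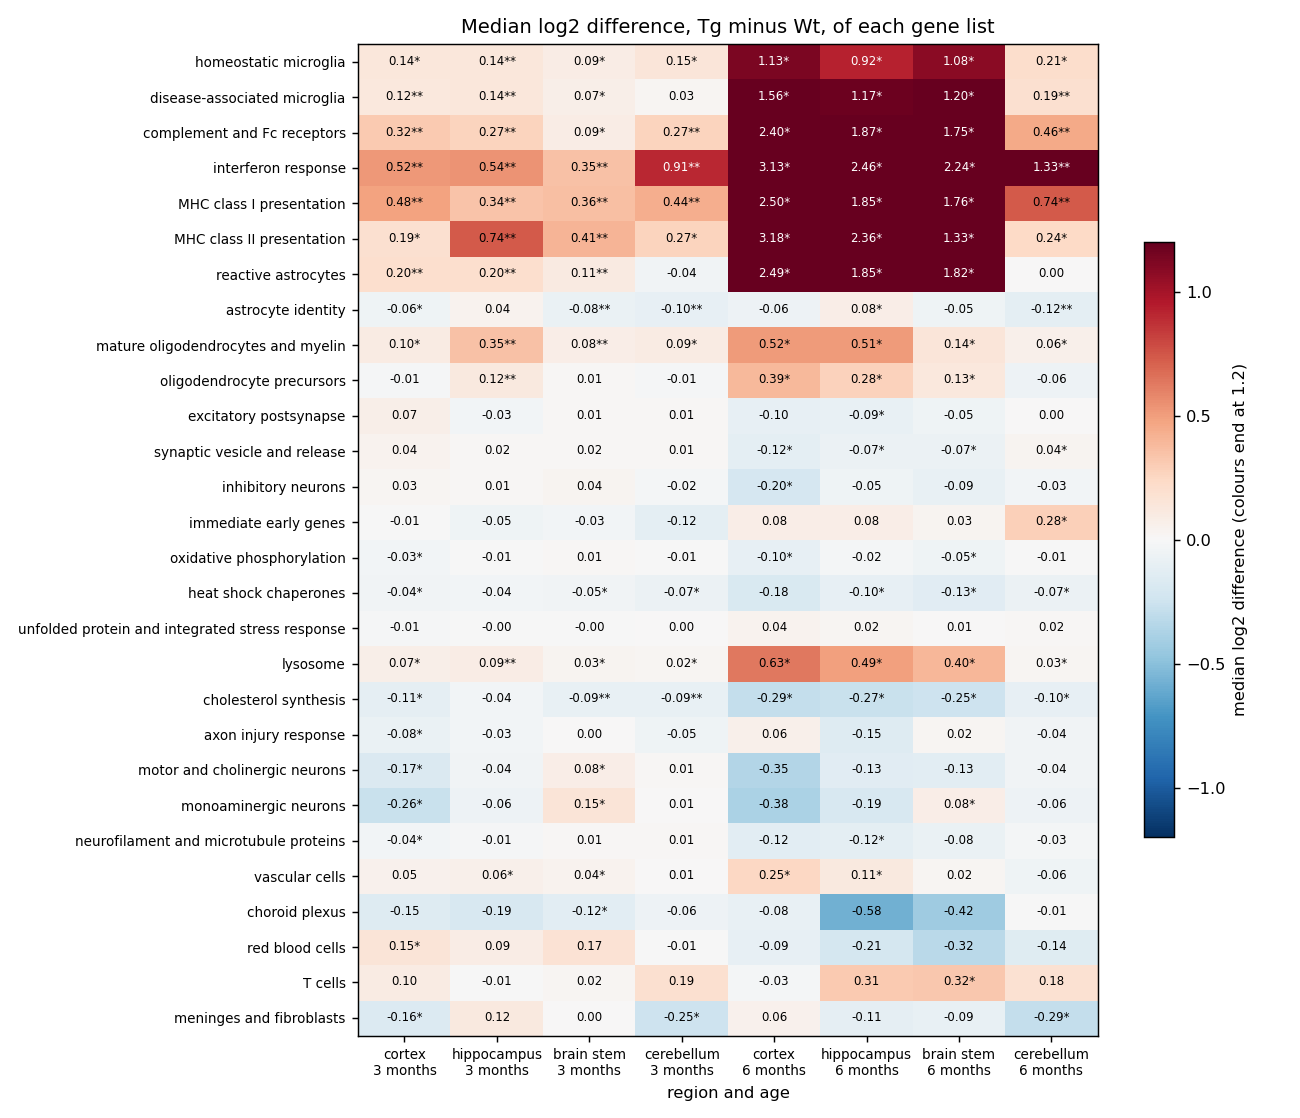
Median Tg minus Wt log2 difference of the members of 28 gene lists (vertical) in the 8 comparisons (horizontal), with the colour scale ending at 1.2. An asterisk marks a camera adjusted p under 0.05 and a double asterisk a call that also held with an estimated correlation, the interferon list reached 3.13 in cortex at 6 months, and scaling turned the sign of T cells (-0.03 to 0.03) and astrocyte identity (-0.06 to 0.0016) in cortex and oxidative phosphorylation (-0.02 to 0.01) in hippocampus at 6 months.

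Across regions and ages 57 of 15390 genes passed with the same sign in all 8 comparisons, 51 up and 6 down, and 20 of them belong to the interferon or MHC class I lists. The genes that fell in all 8 were Gli1, Acaa2, Acat3, Pygm, AA986860 and 2310022B05Rik, named after their values were seen. Of genes up at 3 months, 144 of 162 in cortex, 459 of 506 in hippocampus, 180 of 215 in brain stem and 242 of 386 in cerebellum were also up at 6 months, where independent calls would share 36.7, 94.4, 34.4 and 22.3. Of genes down at 3 months, 61 of 77, 80 of 86, 177 of 212 and 347 of 483 were also down, against 39.7, 35.7, 78.6 and 34.6.

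The age by genotype test asked whether the Tg minus Wt difference changed from 3 to 6 months. In cortex it grew for C4b by 3.22 ± 0.22 (adjusted p = 3.61e-19, Wt 615 at 3 and 875 at 6 months) and for Gfap by 2.58 ± 0.18 (Wt 5129 and 4800.0), and in hippocampus for Gfap by 1.61 ± 0.18. In brain stem C4b grew by 2.58 ± 0.25, and Top2a and Mki67, genes of dividing cells, by 2.44 ± 0.26 (Wt 49.1 and 23) and 2.15 ± 0.24 (Wt 48.2 and 30.6). Where Wt levels were lower in the 6-month table, as for these 2 genes and more so for some immune genes, the size of the growth depends on that level. Trim30a grew by 3.06 ± 0.19 in cortex (Wt 660.5 at 3 and 95.8 at 6 months) and by 0.89 ± 0.11 in cerebellum (Wt 656 and 117), Slfn9 by 1.23 ± 0.19 in cerebellum (Wt 186 and 13.9), Siglec1 by 3.32 ± 0.37 in hippocampus (Wt 89.6 and 9.00), and H2-Q6 by 3.87 ± 0.25 in cortex (Wt 98.8 and 19.8). Such shifts of baseline between the separately normalized tables also enter the list scores. Differences turned more negative for Cbs, which makes cystathionine, in cortex (-0.80 ± 0.10) and hippocampus (-0.49 ± 0.07), for Apln in brain stem (-0.69 ± 0.10) and for Prkg1 in cerebellum (-0.43 ± 0.07). The counts were 7954 of 15720 genes in cortex (2712 up, 5242 down), 4514 of 15707 in hippocampus (1772 up, 2742 down), 3868 of 15746 in brain stem (1537 up, 2331 down) and 62 of 15601 in cerebellum (29 up, 33 down). After median-ratio scaling the majority was up in hippocampus (2217 up, 1733 down) and brain stem (1860 up, 1342 down). By list scores the interferon difference grew by 2.23 ± 0.16, 1.59 ± 0.23 and 1.56 ± 0.22 in cortex, hippocampus and brain stem, and reactive astrocytes by 1.98 ± 0.16, 1.26 ± 0.20 and 1.28 ± 0.19. Vesicle genes moved by -0.15 ± 0.04, -0.12 ± 0.02 and -0.09 ± 0.02 and cholesterol synthesis by -0.20 ± 0.06, -0.21 ± 0.05 and -0.17 ± 0.04. In cerebellum complement was the only list to pass (0.26 ± 0.07, adjusted p = 0.0223), and the interferon difference there moved by 0.26 ± 0.17 (adjusted p = 0.346). Leaving out all libraries of a replicate number gave 8 to 257 genes in cerebellum and 2131 to 4643 in brain stem.

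**Figure D4:**
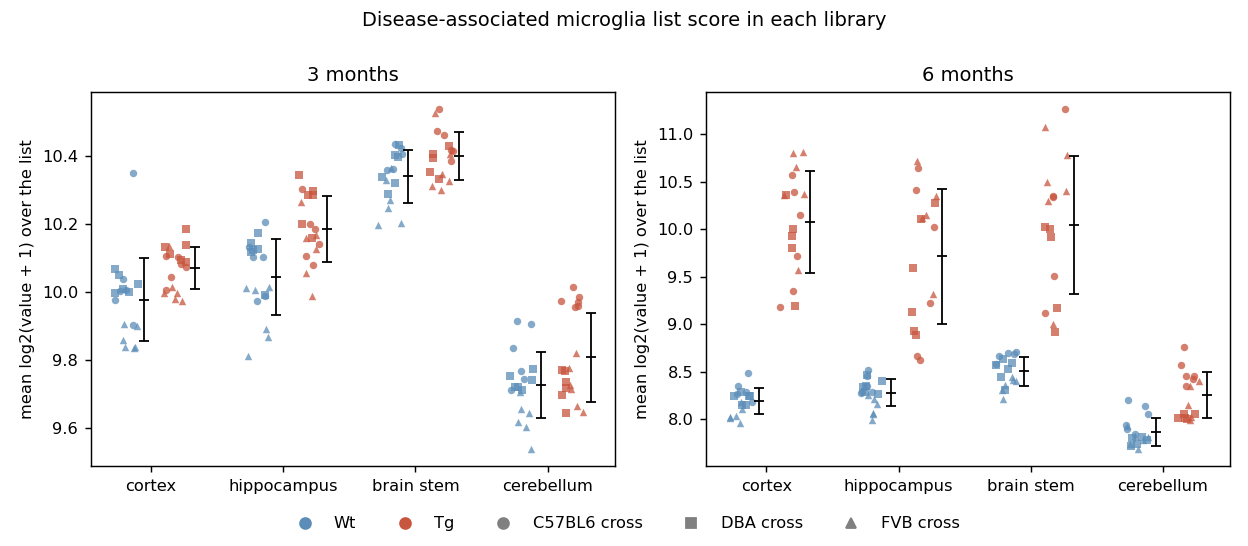
Disease-associated microglia score (mean log2 value of the list) of each library by region, age and genotype, with the cross as marker shape and mean ± SD beside the points. At 6 months cortex Wt libraries of the FVB cross averaged 8.06 ± 0.08 and Tg libraries 10.43 ± 0.47, and scores of both ages are not comparable because each age was normalized by itself.

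The region by genotype test set each region against the cerebellum. At 3 months the Gfap difference was larger in cortex by 1.41 ± 0.16 (adjusted p = 1.12e-09), and that of Prnd by 4 ± 0.19 in cortex and 3.65 ± 0.22 in hippocampus. The Gria1 difference was higher in cortex by 0.39 ± 0.05. Gria1 fell in cerebellum, whereas in cortex it averaged 17881 ± 1568 in Wt and 18906 ± 1183 in Tg, with the libraries that stood apart included. Prokr2, a prokineticin receptor gene, had a lower difference in cortex and hippocampus (-1.10 ± 0.16 and -1.10 ± 0.16), and lower differences were also those of Gli1, at -0.84 ± 0.10 in hippocampus and -0.99 ± 0.11 in brain stem, and Ddx58, a sensor of viral RNA, at -0.75 ± 0.12 in hippocampus. Prokr2 averaged 31.7 in Wt and 59.8 in Tg cerebellum, but 166 and 157 in cortex and 332 and 317 in hippocampus. Ddx58 averaged 275 in Wt and 534 in Tg cerebellum, and 326 and 341 in hippocampus. In brain stem A2m and the myelin-related gene Lgi4 had larger differences by 0.56 ± 0.06 and 0.43 ± 0.05. A2m averaged 4454 in Wt and 3339 in Tg cerebellum, and 934 and 1044 in brain stem. Lgi4 averaged 1789.5 in Wt and 1502 in Tg cerebellum, and 662 and 736 in brain stem. The interferon score difference was smaller than in cerebellum, at -0.44 ± 0.14 in cortex (adjusted p = 0.0310), -0.55 ± 0.13 in hippocampus (8.85e-04) and -0.62 ± 0.14 in brain stem (7.88e-04), whereas reactive astrocytes exceeded it by 0.29 ± 0.06, 0.30 ± 0.05 and 0.16 ± 0.04. The tests passed 102 of 16291 genes for cortex (64 up, 38 down), 496 of 16282 for hippocampus (375 up, 121 down) and 271 of 16302 for brain stem (152 up, 119 down). Without the libraries that stood apart the cortex count was 423, and without the C57BL6 Wt replicate 2 alone 279. Leaving out a replicate number gave 40 to 306, 259 to 418 and 155 to 263 genes, and with the title code as a replicate block brain stem had 407. Libraries of different regions that share a title code were treated as independent, although their residuals correlated positively on average (0.0915 to 0.239).

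At 6 months the cortex and cerebellum differed most. The Gfap difference was larger in cortex by 3.6 ± 0.12 (adjusted p = 1.19e-35), that of the protease inhibitor A2m by 3.88 ± 0.20, of the filament protein Flnc by 4.40 ± 0.27 and of Slc14a1, the urea transporter of astrocytes, by 2.16 ± 0.07. Slc14a1 also had larger differences in hippocampus (1.33 ± 0.08) and brain stem (1.26 ± 0.07), with Dbi, the precursor of a benzodiazepine receptor ligand, at 1.01 ± 0.07 and 0.88 ± 0.07. The Gli1 difference was lower, at -1.33, -1.2 and -1.44 in cortex, hippocampus and brain stem, and that of Igfbp4 at -1.37 and -1.33 in cortex and hippocampus. Igfbp4 rose in cerebellum from 405 ± 151 in Wt to 1121 ± 599 in Tg. In Wt and Tg it averaged 2819 and 2800 in cortex, and 3390 and 3458 in hippocampus. The interferon score difference now exceeded that of cerebellum by 1.75 ± 0.21, 1.01 ± 0.28 and 0.86 ± 0.26, and that of reactive astrocytes by 2.50 ± 0.19, 1.72 ± 0.25 and 1.57 ± 0.23. The tests passed 9943 of 16574 genes for cortex (3203 up, 6740 down), 6559 of 16570 for hippocampus (2530 up, 4029 down) and 4998 of 16590 for brain stem (2081 up, 2917 down).

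The cross by genotype test asked whether the effect of the transgene depended on the partner strain. At 3 months the cerebellum showed it most clearly, in interferon and MHC class I genes that rose little in the DBA cross. B2m, the light chain of MHC class I, rose by 1.06 in the C57BL6 cross, 0.88 in FVB and 0.24 in DBA (adjusted p = 4.33e-04), Ifi27 by 1.35, 1.27 and 0.10, and Irgm1, a GTPase induced by interferon, by 1.31, 0.94 and 0.09. The interferon score rose by 1.42, 1.25 and 0.27 (adjusted p = 2.05e-04), and the MHC class I, homeostatic and disease-associated microglia and complement scores also differed (adjusted p = 2.05e-04, 0.00236, 0.0127 and 0.0134). In brain stem Rufy4 rose by 5.03, 4.36 and 1.13, where its Wt level was already 225 ± 38.5 in the DBA cross, and the falls of Itih3 (-0.75, -1.2 and -0.56), Gli1 and Gpld1 were largest in FVB. These were the 4 brain stem genes that passed (adjusted p = 3.76e-14, 5.68e-06, 0.00209 and 0.0411). In limma 47 of 16083 genes passed in cerebellum and 0 in cortex and hippocampus, where 298 and 544 genes had an unadjusted p under 0.05, fewer than the 811 and 810 expected with no difference. Without the libraries that stood apart, 1 gene passed in each of these regions, which in cortex was so without the C57BL6 Wt replicate 2 alone and in hippocampus without the C57BL6 Tg replicate 6. Leaving out a replicate number gave 10 to 47 genes in cerebellum and 2 to 4 in brain stem.

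At 6 months the crosses differed in cortex for single immune genes, while no immune list passed (interferon score DBA 2.67, FVB 3.76, C57BL6 2.86, adjusted p = 0.0535). The unfolded protein list alone passed there (adjusted p = 0.0443, and 0.0545 with RIN as a covariate). Lcn2, the acute phase protein of reactive astrocytes, rose by 7.20 in FVB, 5.61 in C57BL6 and 1.53 in DBA (adjusted p = 2.70e-04), and Siglecf, an inhibitory lectin receptor, by 4.22, 2.84 and 1.43. In that order Lcn2 averaged 1 ± 0.89, 2.2 ± 1.1 and 44.8 ± 30.3 in Wt and 316 ± 171, 196 ± 155 and 141 ± 140 in Tg. Siglecf averaged 15.7, 18.2 and 44.8 in Wt and 330 ± 110, 152.5 ± 77.1 and 124 ± 32.1 in Tg. The smaller DBA rises of both genes thus started from a higher Wt level. Ifi202b reached 219 ± 109 in DBA and 214 ± 86.5 in FVB Tg but 1.5 ± 1.22 in C57BL6 Tg (adjusted p = 2.80e-06). In brain stem Gli1 fell most in FVB (-2.64 against -1.72 and -1.13), and Rufy4 differed there, as at 3 months, and in hippocampus and cortex (adjusted p = 2.57e-14, 7.97e-10 and 7.83e-06). Among the 9 hippocampal genes were Mfsd2a, a lipid transporter of the blood-brain barrier, and Kdr, the VEGF receptor, which was higher in Tg by 0.31 in DBA and changed by -0.51 in FVB. In cerebellum C1qa rose by 0.84, 0.78 and 0.11 in FVB, C57BL6 and DBA (adjusted p = 2.68e-04), and the interferon score by 1.81, 1.44 and 0.82 (adjusted p = 0.00604). The MHC class I, complement and reactive astrocyte scores differed as well (adjusted p = 0.00206, 0.00206 and 0.00476).

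The counts at 6 months were 1171 of 16480 genes in cortex, 9 of 16473 in hippocampus, 962 of 16519 in brain stem and 183 of 16311 in cerebellum, and those of cortex and brain stem moved with single libraries. Without FVB Tg replicate 5, whose microglia score was the lowest of its group, cortex had 3479 genes and brain stem 3672. In cortex the count was 1893 without C57BL6 Tg replicate 4 and 1818 without DBA Tg replicate 6. It was 752 without DBA Tg replicate 5, 632, 732 and 700 without FVB Wt replicates 1, 4 and 6, and 594, 769, 749 and 540 without FVB Tg replicates 1, 2, 4 and 6. In brain stem it was 1865 without C57BL6 Tg replicate 1, 581 and 586 without DBA Tg replicates 4 and 5, 637 without FVB Wt replicate 4, and 557 without FVB Tg replicate 1. With RIN as a covariate cortex had 93 genes, hippocampus 2 and brain stem 619. Hippocampus had 20 after scaling and 28 with the larger pseudocount. Leaving out a replicate number gave 80 to 3192 genes in cortex, 1 to 331 in hippocampus, 224 to 2370 in brain stem and 14 to 259 in cerebellum.

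Among Wt libraries the partner strain changed 19.4% to 33.7% of genes. Pttg1, securin of the mitotic spindle checkpoint, was lower in both the DBA and FVB than in the C57BL6 cross in cortex (-0.92 ± 0.05 and -0.94 ± 0.05). Tuba1c was higher in brain stem (3.73 ± 0.14 in DBA, 4.97 ± 0.14 in FVB), and the amino acid transporter gene Slc7a3 lower in cerebellum (-3.00 ± 0.09 and -2.63 ± 0.09). Serpina3n, a protease inhibitor that astrocytes raise in inflammation, was higher in FVB than in C57BL6 cerebellum by 2.94 ± 0.05 (adjusted p = 3.41e-35), with 912 ± 31.2 against 118 ± 9.50. Rufy4 was higher in DBA brain stem by 4.71 ± 0.17. The DBA cross differed in 3582, 5051, 5255 and 5246 genes and the FVB cross in 3050, 3964, 4722 and 5044 in cortex, hippocampus, brain stem and cerebellum. The C57BL6 reference of cortex, where counts were lowest, included the 3-month Wt replicate 2 library, whose region and cross are in doubt. Strain variants can change how reads of an allele align, and alignment was not examined here.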

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

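All tests of explanations and all splits in this part were chosen only after the results were seen.

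Genes beside Prnp formed the sharpest difference between Tg and Wt. The genes 5330413P13Rik, Erv3, Prnd and Rassf2 were higher in Tg in all 8 comparisons, Prnp between them moved by -0.07 to 0.09, and the next measured genes outward, Gm14285 and Slc23a2, were higher in 0. A response to tau that builds up with age is argued against, since the median change of the difference from 3 to 6 months over these genes and cortex, hippocampus and brain stem was 0.0171 (from -0.61 to 0.18). Extra copies of DNA from beside Prnp carried with the transgene are neither upheld nor excluded, since of the 3 measured genes inside the outermost raised ones 2 were raised and Prnp was not. The stretch is set by the raised genes themselves, and copy number was not measured.

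A second group, Rufy4 (2.16 to 3.9), Plcd4, Zfp142 and Bcs1l, neighbours on another chromosome, was higher in Tg in all 8 comparisons. For Zfp142 and Bcs1l the Tg minus Wt difference changed little from 3 to 6 months (median change -0.0653, from -0.16 to 0.02). For Rufy4 and Plcd4 the median change was 0.546 (from 0.13 to 1.26). That median includes 3-month cortex, where the C57BL6 Wt group holds the replicate 2 library doubted below. Rufy4 and Plcd4 averaged 47 ± 109 and 751 ± 401 in that group, and 1 and 570 in FVB Wt. Rufy4 was also low in 3-month hippocampus of FVB and C57BL6 Wt (3.5 in each), where log2 changes depend on small values. In the DBA cross the Rufy4 log2 difference in brain stem was 1.13 at 3 and 1.07 at 6 months. Rufy4 in DBA hippocampus averaged 81.2 in Tg and 35.7 in Wt at 3 months, and 149 and 63.7 at 6 months. In DBA cortex it averaged 60.7 and 30.3 at 3 months, and 152 and 52.2 at 6 months. The pairs were formed after the undivided group gave no verdict (median 0.0766), and they separate larger from smaller values of the tested change itself. The pair tests therefore cannot decide on a response to tau that grows with age, which stays open. Tns1, next to Rufy4, was higher in Tg in 5 of 8 comparisons. It was also higher in DBA than C57BL6 Wt in hippocampus (0.49) and brain stem (0.61). In 3-month cortex the C57BL6 Wt mean of Tns1 (3490 ± 2037, Tg 3040 ± 133) includes the same doubted library. Tns1 there averaged 2949 in Wt and 3422 in Tg of the DBA cross, and 2610 and 3044 in FVB. A DBA-type strain variant beside the insertion is argued against for Plcd4, Zfp142 and Bcs1l, as the DBA minus C57BL6 difference in Wt plus 2 SE lay below the Tg difference in 12 of 12 gene by region values. That bound replaced a bound pooled over regions that had left Plcd4 undecided, and for Rufy4, and for Tns1, which was not in the test, the variant stays open, since Rufy4 was higher in DBA Wt in 4 of 4 regions.

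The C57BL6 replicate 2 libraries of 3-month cortex stood apart in Wt and Tg. In Wt the cortex marker score was 7.59, inside the range of brain stem libraries (7.15 to 8.34), and its correlation was 0.995 with the brain stem mean and 0.921 with the cortex mean. A swap with a brain stem library of the series is argued against (0 such libraries had a cortex-level score), and a whole brain stem sample under a cortex label stays open (7.59), with its cross also in doubt, as its Rufy4 value was 270 where brain stem Wt libraries averaged 9.80 in the C57BL6 and 225 in the DBA cross. In Tg a whole cerebellum sample is argued against (score 11, cerebellum 5.75 to 7.28), and cerebellar RNA mixed into a cortex sample stays open, with 53.7% needed (quartiles 51.5% to 56.5% over 100 transcripts). No biological explanation was tested, and both libraries stayed in the analysis under their labels.

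In 15 of 144 tests Dixon's rule picked a group with a library far from the others, where chance picks about 1 in 20 groups (7.2 here). For Mapt these were brain stem at 6 months DBA Wt replicate 6 (28729, others 26146 to 26500), cerebellum C57BL6 Tg replicate 1 at 3 months (30722, others 32336 to 32597) and replicate 2 at 6 months (35244, others 32504 to 33398), and cortex at 3 months C57BL6 Tg replicate 2 (33668, others 29894 to 30978). For the disease-associated microglia score they were FVB Tg replicate 5 at 6 months in brain stem (9.00, others 10.30 to 11.07) and cortex (9.57, others 10.36 to 10.82) and at 3 months in cortex (10.14, others 9.97 to 10.02), cortex at 3 months C57BL6 Wt replicate 2 (10.35, others 9.90 to 10.04) and hippocampus at 3 months DBA Wt replicate 3 (9.99, others 10.12 to 10.17). For the marker score of the own region they were the C57BL6 replicate 2 cortex libraries above, DBA Tg replicate 5 (11.94, others 11.77 to 11.81) and FVB Tg replicate 5 (11.79, others 11.62 to 11.66) of 6-month cortex, and DBA Tg replicate 2 (10.96, others 11.20 to 11.31) and FVB Wt replicate 2 (11.24, others 11.47 to 11.52) of 6-month hippocampus.

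The Tg effect differed between crosses in 1171, 9, 962 and 183 genes at 6 months in cortex, hippocampus, brain stem and cerebellum, and in 4 and 47 genes at 3 months in brain stem and cerebellum. It differed between ages in 7954, 4514, 3868 and 62 genes in cortex, hippocampus, brain stem and cerebellum. Against cerebellum it differed in 102, 496 and 271 genes at 3 months and in 9943, 6559 and 4998 at 6 months in cortex, hippocampus and brain stem.

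Genes held only in the 6-month files of single libraries, outside the comparisons of the report, were higher in Tg in 47 (cortex), 10 (hippocampus), 8 (brain stem) and 2 (cerebellum) of 1555, 1609, 1524 and 1699 tested, and more of them were lower in Tg (272, 86, 64 and 3).

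Of 34 counts of genes, 30 were reached in 1 of 100 splits of the libraries, the real one. That is a level of 1 in 100 for each count, not adjusted over the 34. Real differences stay in the shuffled data as spread, so low counts in other splits do not show that the size of a count is stable. For Tg against Wt the highest other count was 142 (real 247), 216 (603), 193 (431) and 2 (878) at 3 months and 0 (12219), 4305 (9907), 7060 (8769) and 16 (2084) at 6 months in cortex, hippocampus, brain stem and cerebellum. For crosses it was 1 (4) and 10 (47) in brain stem and cerebellum at 3 months and 0 (1171), 3 (9), 1 (962) and 113 (183) in the 4 regions at 6 months. For ages it was 0 (7954), 2 (4514) and 11 (3868) in cortex, hippocampus and brain stem. For regions it was 59 (496) and 77 (271) in hippocampus and brain stem at 3 months and 1 (9943), 3 (6559) and 1 (4998) at 6 months. Among Wt crosses it was 1193 (3582), 7 (5051), 4 (5255) and 2798 (5246) for DBA and 784 (3050), 0 (3964), 1 (4722) and 26 (5044) for FVB. The age count in cerebellum (62, highest other 486) and the 3-month count of cortex against cerebellum (102, highest other 307) were reached in 2 of 100 splits, and such high other counts point to a structure of the samples, the source of which was not tested. The 3-month counts of 0 for crosses in cortex (highest other 2) and hippocampus (highest other 1) are reached by all 100 splits by construction, so the splits decide nothing there.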

How the results depend on the processing

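The tests after scaling, with the larger pseudocount, without the doubted libraries and without single libraries were chosen only after results were seen. The 3 doubted libraries were picked by their values with no criterion set beforehand. The 4 comparisons of 6 with 3 months in Wt were not run, as each age was normalized by itself, and alternatives that need counts were not run. Depth is unknown, so its limits were not measured. Counts of genes stayed within 1.5 times for 33 of 34 results after scaling, 33 of 34 with the pseudocount, 34 of 34 without a filter, 31 of 34 with RIN, 13 of 14 with a replicate block and 6 of 10 without the doubted libraries. Of 224 list tests 119 passed, and 87 of these lost the call with an estimated correlation. Named genes kept direction and call in 940 of 952 cases after scaling and 943 of 952 with RIN.

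For the following values the cause was not tested. Without the doubted libraries Tg against Wt in cortex at 3 months gave 893 genes, the crosses in cortex and hippocampus at 3 months 1 each, and cortex against cerebellum at 3 months 423. With RIN the crosses at 6 months gave 93 (cortex), 2 (hippocampus) and 619 (brain stem). For the crosses in hippocampus at 6 months scaling gave 20 and the pseudocount 28. For regions against cerebellum the replicate block was the title code. There were 72 codes for 277 libraries. Residuals of libraries with the same code correlated by 0.0915 to 0.239 on average (other codes -0.0472 to -0.0182). Single pairs ran from -0.181 to 0.747. Whether a code marks 1 animal is not known, and negative single pairs do not exclude it. The main region tests treated such libraries as independent. The block gave 95, 608 and 407 genes at 3 months and 9991, 6515 and 5381 at 6 months for cortex, hippocampus and brain stem.

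With a replicate number or 1 library left out, the lowest and highest counts for Tg against Wt were 143 and 644 (cortex, 3 months), 357 and 717 (hippocampus, 3 months), and 1389 and 1969 (cerebellum, 6 months). For crosses they were 0 and 1 in cortex and hippocampus, 2 and 4 in brain stem and 10 and 47 in cerebellum at 3 months, and 80 and 3479 in cortex, 1 and 331 in hippocampus, 224 and 3672 in brain stem and 14 and 259 in cerebellum at 6 months. For ages they were 2131 and 4643 in brain stem and 8 and 257 in cerebellum. For regions at 3 months they were 40 and 306 (cortex), 259 and 540 (hippocampus) and 155 and 263 (brain stem). Of the named genes only Prnp turned direction, at values near 0 that never passed: brain stem at 6 months 0.0193 after scaling and from -0.0383 (without replicate 1) to 0.00298 (without replicate 2), cerebellum at 3 months from -0.00988 (without replicate 3) to 0.00690 (without replicate 2), and cerebellum at 6 months from -0.0109 (without replicate 5) to 0.0249 (without replicate 6), with -0.000235 without replicate 2.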

Other observations

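The tests of genes held only in files of single libraries were chosen only after those files were seen. In cortex at 6 months H2-Ea-ps, a pseudogene of MHC class II, was higher in Tg by 1.84 ± 0.28 on the log2 scale, and Vmn2r86 was lower (-1.05). In hippocampus Trpa1, an ion channel gene, was lower (-0.97), and in cerebellum Styk1 was higher by 0.96. These 4 genes were named after their values were seen.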
